A study of Mus musculus with 9 samples.

How the data were processed

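Total RNA of 9 mouse tumour samples was measured by RNA sequencing in 3 groups of 3: N134 subcutaneous tumours, N134-RHAMMB subcutaneous tumours and N134-RHAMMB liver metastases. Per the labels' protocols, RNA was extracted with a Qiagen column kit that also keeps small RNA, after homogenisation on shredder columns. The library preparation, the strand setting and the read length are not given in the sources used here. Per the submitters' processing notes, bcl2fastq 2.19, STAR 2.5.2 and Cufflinks 2.1.1 were used with the GRCm38 build, and the notes do not state the role of each tool. The authors deposited 1 table of FPKM values, fragments per kilobase of transcript per M (mega) mapped fragments, for 22053 rows of protein-coding genes in all 9 libraries, with a status word for each value, per the file headers. FPKM divides by gene length and by library size before deposit, so a gene's value falls when other genes take more of the library, and counts are not used here.

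7 rows with a failed estimate in any library (Phf3, Rif1, Rpl22, Nup205, Kmt2d, Ppp1r10 and Gnl3l) were left out. 102 rows that repeated a gene symbol at another locus were dropped in favour of the locus with the highest mean, which left 21944 genes. Low-data status in at least 1 library (40 rows) was not a reason to drop a gene. The 12854 genes with FPKM of at least 1 in at least 3 libraries were tested. Values were log2(FPKM + 1), and every fold change is on this scale, which understates the change of low genes. A value of 0 in the table can be a failed estimate, so a gene at 0 in all libraries of a group is said to be listed at 0 and is given no fold change against that group. Without counts or strand information, genes with near-identical copies (globins, Serpina1 and Serpina3 families, Gstm, Ins1 and Ins2, class I histocompatibility genes) and overlapping genes have uncertain values.

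Gene coordinates are those of the table in GRCm38, with 1 added to the start, since 82.2% of 21887 rows matched by gene ID to GENCODE release M21 of the same build had a start 1 below the annotated one. Depth was estimated from single-fragment steps: in genes with 1 transcript of 2000 to 6000 nucleotides, the lowest values of a library cluster at the FPKM of 1 fragment. This gave 14.5 (N134-RHAMMB tumour 4) to 17.8 (metastasis 2) M fragments, and 1 fragment in a transcript of 2 kb was worth 0.0281 to 0.0346 FPKM. The threshold of 1 FPKM therefore lay above the value of 1 fragment in such a transcript in every library. Sums of FPKM were 436861 to 466014, and median-of-ratios factors 0.929 to 1.08.

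Group differences were tested with limma 3.58.1 in R 4.3.3, with 1 linear model over all 9 libraries. The groups then share 1 estimate of the spread (6 residual degrees of freedom). The prior variance had an intensity trend, and tests were 2-sided with Benjamini-Hochberg adjustment over all genes, at adjusted p below 0.05. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1 and was not used for single genes. The comparisons were N134-RHAMMB against N134 tumours, metastases against N134-RHAMMB tumours and metastases against N134 tumours. They share groups, so no overlap or correlation between them is reported. 35 gene lists of cell types, islet functions and pathways were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists with at least 3 measured members. They were tested again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. Of 629 list genes, 485 were measured, 136 lay under the filter and 8 had no row of that symbol. The lymphocyte list had 1 measured member, Cd4, whose log2 differences in the 3 comparisons were 0.32, -0.82 and -0.50, and was not tested. Figures were drawn in Python 3.11.15.

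The groups, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. Genes are named if they passed, had a mean of at least 5 FPKM in the higher group and had groups that did not overlap (chance gives 10% for 3 against 3). They are the 10 largest changes each way and, for the comparisons with metastases, also the 10 largest each way among genes at that mean in both groups. Hmmr is named too, and 2 to 4 members with the largest absolute change of each list described, passing or not. Genes named only by a clone or a predicted-gene number were passed over, and the text may stop at 20 genes per comparison in order of size. Some genes that the rule selects, and 1 list, are not reported here. Alternatives were another pseudocount (0.1), no filter and a stricter one, median-of-ratios scaling, quantile normalization and only the 2 groups compared. Others were different variance models, library weights, the replicate number as a block, each library left out, a minimum size of change and the other set tests. Leaving out N134-RHAMMB tumours 2 and 4 was chosen after seeing the data. The steps were tested on simulated data with 50 genes changed at each of 4 sizes among 12854. Of genes changed 2-, 4-, 8- and 16-fold, 68%, 98%, 96% and 100% were recovered for N134-RHAMMB against N134 tumours. The shares were 72%, 98%, 100% and 100% for metastases against N134-RHAMMB tumours and 76%, 94%, 100% and 100% for metastases against N134 tumours. Of unchanged genes, 17, 11 and 7 were called in the 3 comparisons. The simulated noise was normal, independent between genes and of equal spread in all groups. The real libraries hold an outlying metastasis and genes that move together, so these shares do not give the power of the real comparisons.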

Results

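RNA was sequenced from 9 mouse tumour samples in 3 groups of 3. N134 is a mouse pancreatic neuroendocrine tumour cell line, and N134-RHAMMB is the line named for RHAMMB, an isoform of the hyaluronan-binding protein RHAMM that the gene Hmmr encodes. Cells were injected under the skin or into the tail vein of NSG mice, which lack mature B, T and natural killer cells. Subcutaneous tumours were taken from N134 (N134 tumours 1, 2 and 3) and N134-RHAMMB (N134-RHAMMB tumours 1, 2 and 4), and liver metastases from N134-RHAMMB (metastases 1, 2 and 3). The study's title states its subject as the part RHAMMB plays in metastasis, which the comparisons address at the level of RNA. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

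Insulin transcripts led all 9 libraries. Ins2, which encodes insulin, took the largest share of FPKM, from 4.69% to 8.42% per library. The 10 most abundant genes together took 11.8% to 15.8%. Iapp, which encodes the islet peptide amylin, averaged 3449, 3437 and 3894 FPKM in N134 tumours, N134-RHAMMB tumours and metastases. Each library held 12057 to 12542 genes at 1 FPKM or more, and the estimated depth was 14.5 to 17.8 M fragments (M, mega). Between libraries of a group, Pearson's r across genes was 0.986 to 0.988 in N134 tumours, 0.982 to 0.988 in N134-RHAMMB tumours and 0.946 to 0.979 in metastases. The first principal component held 61.9% of the variance and parted metastases from subcutaneous tumours. The next held 13.1%, with metastasis 2 away from the other metastases.

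**Figure D1:**
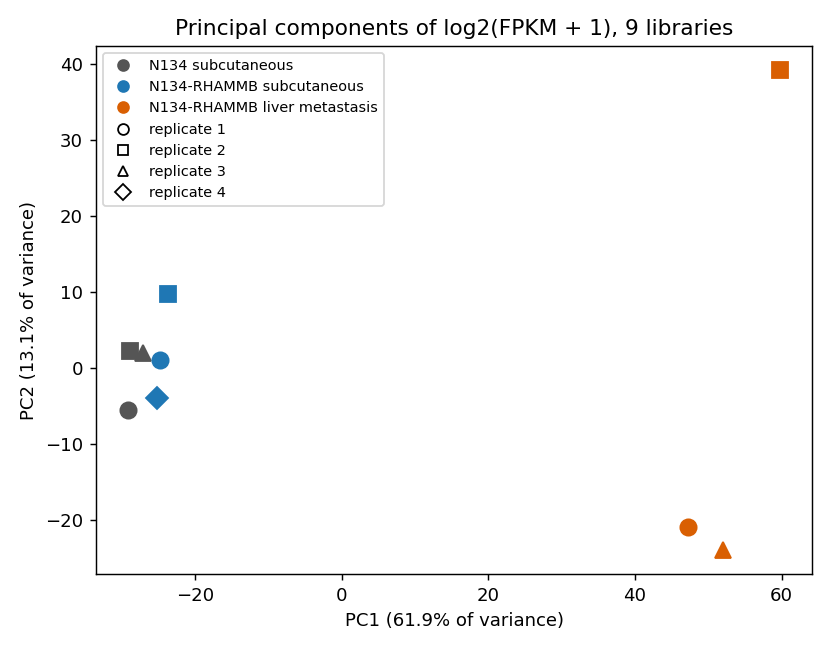
Each point is 1 library, placed by the first and second principal components of log2(FPKM + 1) over 12854 genes, which hold 61.9% and 13.1% of the variance, with the groups in different colours. The 3 metastases lie apart from the 6 subcutaneous tumours, and metastasis 2 lies apart from metastases 1 and 3.

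Hmmr (ENSMUSG00000020330, chromosome 11, 40701395 to 40733422) was read in every library. It stood at 44.9, 39.2 and 42.7 FPKM in N134 tumours, 50.2, 51.3 and 49.2 FPKM in N134-RHAMMB tumours and 36.0, 40.0 and 43.3 FPKM in metastases. The means were 42.2 ± 2.86, 50.2 ± 1.04 and 39.8 ± 3.65 FPKM (SD, n = 3). On the log2(FPKM + 1) scale, N134-RHAMMB tumours differed from N134 tumours by 0.25 (SE 0.10, limma adjusted p = 0.354). Metastases differed from N134-RHAMMB tumours by -0.33 (adjusted p = 0.0991). From N134 tumours metastases differed by -0.09 (adjusted p = 0.708). None of the 3 differences passed. With library weights in limma the first reached adjusted p = 0.0315 and the second 0.0175. These were the lowest values over all alternatives, and the highest were 0.884 and 0.575. The species and sequence of the RHAMMB construct are not given in the sources used here, so the Hmmr value need not include its transcript and does not check the labels.

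The comparison of N134-RHAMMB with N134 tumours, both grown under the skin, asks how the RHAMMB line differs at the same site. Gip (ENSMUSG00000014351, chromosome 11, 96024545 to 96030831), which encodes the incretin hormone glucose-dependent insulinotropic polypeptide, fell the most, from 90.3 ± 5.39 to 3.53 ± 2.65 FPKM (SD, n = 3), a log2 change of -4.55 (SE 0.40, adjusted p = 0.00539). Ephx1 (ENSMUSG00000038776, chromosome 1, 180976210 to 181020904), the microsomal epoxide hydrolase, rose from 14.6 ± 1.26 to 37.9 ± 2.1 FPKM (1.32, SE 0.14, adjusted p = 0.0140). As groups, transcripts of fibroblasts and macrophages were lower in N134-RHAMMB tumours in a set test, with a median log2 change of -0.85 and -0.67. Over all genes 2 of 20 and 0 of 20 members passed in limma (16 and 17 at an unadjusted p under 0.05), and both list calls were lost (adjusted p = 0.375 with an estimated correlation for each). Over all genes limma called 25 of 12854, 10 higher and 15 lower in N134-RHAMMB tumours.

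Among other genes of the naming rule, Gng4, a G protein gamma subunit (-1.51, 32 ± 4.45 to 10.5 ± 0.865 FPKM), fell, as did the complement component C3 (-1.42, 6.04 ± 1.85 to 1.60 ± 0.420 FPKM). So did Pdgfra, a growth factor receptor of fibroblasts (-1.36, 6.30 ± 0.592 to 1.84 ± 0.192 FPKM). Dcn, which encodes the collagen-binding proteoglycan decorin, fell from 26.8 ± 2.11 to 12.3 ± 2.29 FPKM (-1.07). Ero1lb, an endoplasmic reticulum oxidase that helps proinsulin to fold, fell from 79.8 ± 11.7 to 44.2 ± 2.57 FPKM (-0.83). Vopp1 (-1.13), Rprml (-0.78) and Gmnn (-0.57), which encodes the replication licensing inhibitor geminin, fell too. Sgk2, a serum- and glucocorticoid-regulated kinase, rose from 8.75 ± 1.56 to 19.4 ± 2.79 FPKM (1.07). Ppp1r14a, an inhibitor of myosin phosphatase (1.18), Pnma2, a paraneoplastic antigen (1.06), and Fbxo2, an F-box protein that binds N-glycans (1.0), rose. The sulfotransferase Sult4a1 (0.96), Cmbl (0.95) and the mitochondrial ribosomal protein Mrpl34 (0.63) also rose. Adjusted p for these genes was 0.0140 to 0.0492. In each the 3 values of one group lay outside those of the other.

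**Figure D2:**
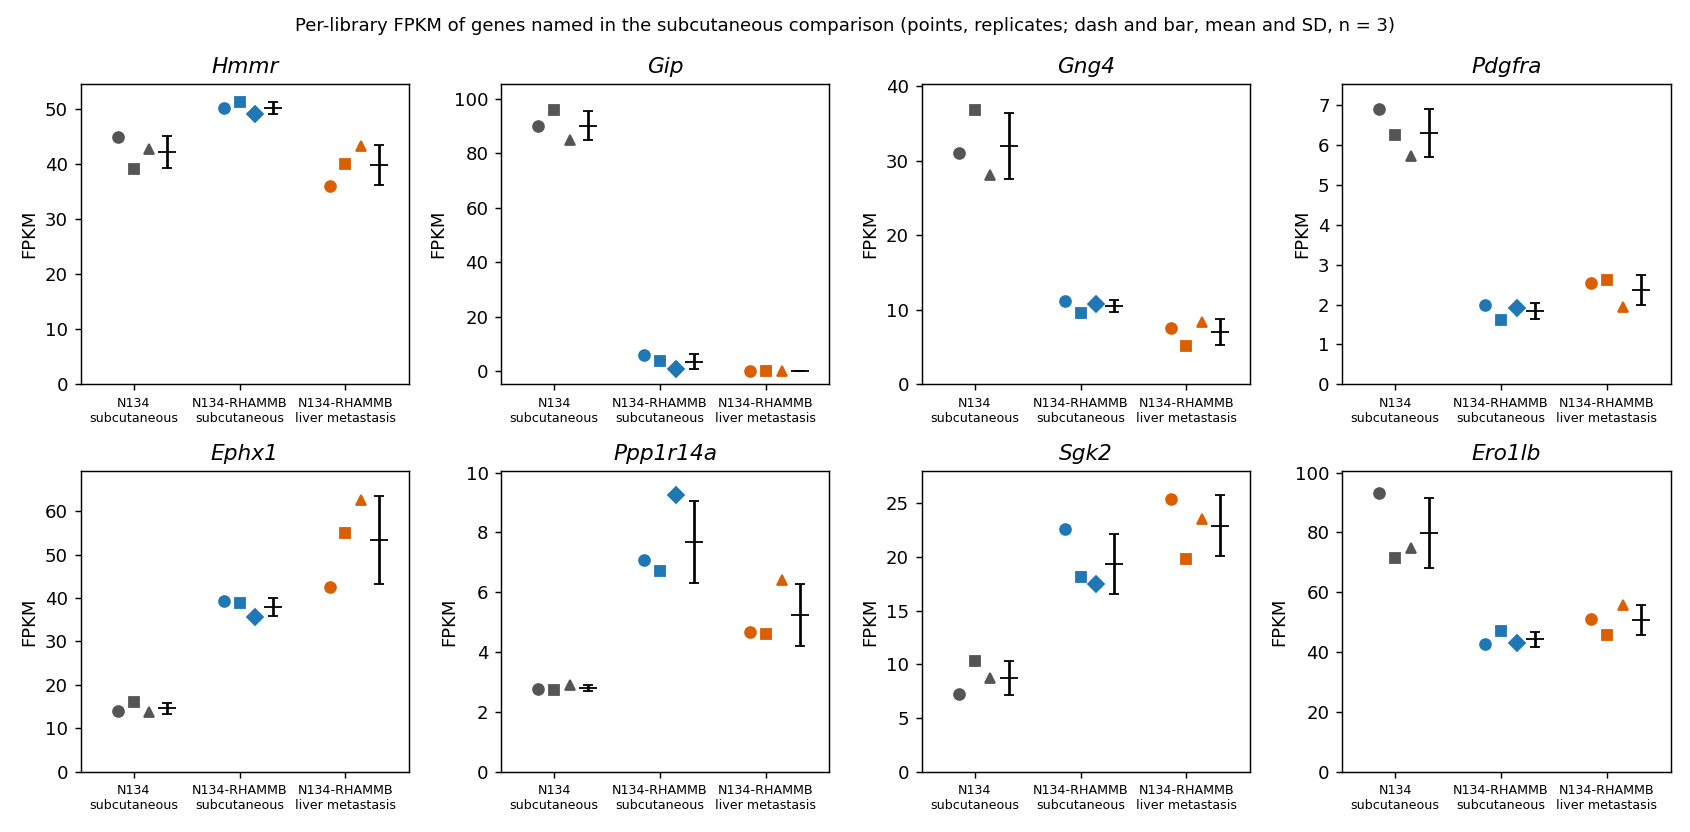
FPKM of Hmmr and of genes named in the comparison of the subcutaneous tumours, with 1 point per library, and the mean and SD of each group of 3. Gip lies at 85.1 FPKM or more in every N134 tumour and at 6.05 FPKM or less in every N134-RHAMMB tumour, while Hmmr lies between 36.0 and 51.3 FPKM in all 9 libraries.

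Of 20 measured fibroblast and matrix genes, 2 fell over all genes tested (Pdgfra and Dcn) and 18 did not pass. Of the 20, 16 were lower when adjusted over the list alone. Their median was -0.85 (camera adjusted p = 7.4e-15; adjusted p = 0.375 with an estimated correlation). Mmp2, a matrix metalloproteinase, stood at -1.17 (adjusted p = 0.0663) and Fn1, fibronectin, at -1.14 (adjusted p = 0.133). The macrophage list had a median of -0.67 (adjusted p = 5.43e-13; adjusted p = 0.375 with an estimated correlation). In it 0 of 20 members passed in limma over all genes, 17 had an unadjusted p under 0.05, and 16 were lower when adjusted over the list alone. Cd14, the lipopolysaccharide co-receptor, was at -1.02 (adjusted p = 0.102) and Trem2 at -0.91 (adjusted p = 0.276). The erythroid list was lower with a median of -1.21 (adjusted p = 2.2e-05; adjusted p = 0.375 with an estimated correlation). None of its 4 members passed over all genes in limma, 4 had an unadjusted p under 0.05, and 4 were lower when adjusted over the list alone. Hba-a1 stood at -1.53 and Hbb-bt at -1.22, globin genes whose near-identical copies make single values uncertain.

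Proteases and their regulators were lower (median -0.50, adjusted p = 2.28e-04; adjusted p = 0.423 with an estimated correlation), with 2 of 17 lower when adjusted over the list alone. Timp1, a metalloproteinase inhibitor, stood at -1.27 (adjusted p = 0.261). Pericyte and stellate cell genes were lower (median -0.35, adjusted p = 3.38e-04; adjusted p = 0.423 with an estimated correlation), with 1 of 15 lower when adjusted over the list alone. Tagln stood at -1.0 and Acta2, smooth muscle actin, at -0.96. Hypoxia and glycolysis genes were lower (median -0.26, adjusted p = 8.92e-04; adjusted p = 0.518 with an estimated correlation), with 1 of 23 higher and 1 lower when adjusted over the list alone. Pfkl, a phosphofructokinase, stood at -0.65 and Ldha, lactate dehydrogenase, at -0.61. Kupffer cell genes were lower (median -0.33, adjusted p = 0.0377; adjusted p = 0.564 with an estimated correlation), with Cd5l at -0.99 and the scavenger receptor Marco at -0.83. So were Y-linked genes (median -0.35, adjusted p = 0.0377; adjusted p = 0.423 with an estimated correlation), with Ddx3y at -0.42 and Eif2s3y at -0.35. Immediate-early and stress genes were lower too (median -0.24, adjusted p = 0.0455; adjusted p = 0.621 with an estimated correlation), with the transcription factors Egr1 at -1.0 and Fos at -0.85. Of these 3 lists, 1 of 3 Y-linked members was lower when adjusted over the list alone. In these 6 lists no member passed over all genes in limma, against 8, 4, 8, 1, 1 and 1 at an unadjusted p under 0.05.

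Oxidative phosphorylation had a median of 0.17 over 25 members (adjusted p = 0.00337; adjusted p = 0.428 with an estimated correlation). Of these, 0 passed in limma over all genes, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. Cox7a2 stood at 0.31 and Cox5b at 0.29, both subunits of cytochrome c oxidase. Skeletal muscle transcripts moved with 2 of the libraries. Of 14 muscle genes in the table, 12 and 14 reached 1 FPKM in N134-RHAMMB tumours 2 and 4, against 2 in N134-RHAMMB tumour 1 and 2 or 3 in each other library. Ckm, muscle creatine kinase, stood at 10.2 and 16.0 FPKM in those 2 tumours and at 0.0582 FPKM or less elsewhere. The 3 members past the filter, led by Tnni2 (2.11) and Mylpf (2.09), had a median of 2.09 (adjusted p = 8.92e-04; adjusted p = 0.375 with an estimated correlation). In limma 0 passed over all genes, 3 adjusted over the list alone and 3 at an unadjusted p under 0.05. Without those 2 tumours the muscle median was -0.06, and limma called 1 gene.

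In all, 22 lists did not pass. Among them were beta cell secretory genes (median 0.13, adjusted p = 0.913), islet transcription factors (-0.08, adjusted p = 0.726), cell cycle genes (0.09, adjusted p = 0.139) and endothelial genes (-0.10, adjusted p = 0.164). The hyaluronan list, which holds Hmmr, had a median of -0.01 and a mean of 0.04 with the test in the direction of the mean (adjusted p = 0.391). Cd44, a hyaluronan receptor, stood at 0.43 (adjusted p = 0.207). Median, mean and test also differed in sign for the keratinocyte, class I, neuronal and other islet hormone lists. With an estimated correlation between genes, camera called 0 of 34 lists, 4 had an unadjusted p under 0.05, and fry called 1.

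The count of 25 genes, beside 1648 at an unadjusted p under 0.05, depended on single libraries. In limma it was 0 without N134 tumour 1, 2 or 3 (1274, 1091 and 1322 at an unadjusted p under 0.05). It was 8, 2 and 2 without N134-RHAMMB tumour 1, 2 and 4, and 193 without metastasis 2. The 6 subcutaneous libraries alone gave 169, library weights 2629 and a mean of at least 5 FPKM 15. The immediate-early list lost its call without N134 tumour 2 or 3, or N134-RHAMMB tumour 2 (adjusted p = 0.0594 to 0.197). The Kupffer list lost its call without N134 tumour 2, or N134-RHAMMB tumour 2 or 4, or metastasis 2 (adjusted p = 0.0543 to 0.232). The Y-linked list lost its call without N134 tumour 2, or N134-RHAMMB tumour 1, or metastasis 2 (adjusted p = 0.0572 to 0.139). The hypoxia list lost its call without N134 tumour 2 (adjusted p = 0.0583). The oxidative phosphorylation list lost its call without N134-RHAMMB tumour 2 (adjusted p = 0.191).

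The comparison of liver metastases with N134-RHAMMB subcutaneous tumours holds the cell line and changes the site. Cells were injected under the skin or into the tail vein, so site and route of injection cannot be told apart. Hepatocyte transcripts had the largest list median. In limma 31 of 35 measured members rose over all genes tested and 32 when adjusted over the list alone, and the median log2 change was 5.56 (camera adjusted p = 1.26e-67; adjusted p = 0.00258 with an estimated correlation). Alb (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), which encodes serum albumin, rose from 0.629 ± 0.129 to 1508 ± 99.2 FPKM (SD, n = 3; 9.86, SE 0.12, adjusted p = 2.31e-11). The matrix, protease and cell cycle lists were lower in the set test, with 6 of 20 (and 1 higher), 4 of 17 and 1 of 30 members lower over all genes. All 3 list calls were lost with an estimated correlation: adjusted p = 0.562, adjusted p = 0.562 and adjusted p = 0.534. Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799), a monocyte-attracting chemokine, fell the most, from 55.3 ± 3.01 to 0.179 ± 0.183 FPKM (-5.59, SE 0.40, adjusted p = 3.54e-06). Over all genes limma called 843, 648 higher and 195 lower (76.9% higher). With quantile normalization 66.7% were higher, 630 against 314.

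Plasma proteins made by the liver led the genes that rose. Ahsg, fetuin-A (8.46), Hpx, the haem carrier hemopexin (8.25), Apoa1, the main protein of high-density lipoprotein (7.02), and Serpinc1, antithrombin (6.97), rose. So did Gc, the vitamin D binding protein (6.74), and Fga, a fibrinogen chain (6.73), with Cyp2e1, a cytochrome P450 (6.82), the serpin Serpina3k (8.01) and the glutathione transferase Gstm3 (7.19). Near-identical paralogs make the values of Serpina3k and Gstm3 uncertain. Among genes at a mean of 5 FPKM or more in both groups, Apoa2 (6.61), Trf, transferrin (5.02, 40.3 ± 6.66 to 1336 ± 163 FPKM), and Hp, haptoglobin (4.82), rose. Mgst1, a microsomal glutathione transferase (4.72), Apoc3 (4.09), Spp1, osteopontin (3.76, 5.70 ± 4.46 to 78.7 ± 11.4 FPKM), and Apoe (3.01, 149 ± 48.8 to 1165 ± 59.3 FPKM) rose. In that subset 135 genes were higher and 91 lower.

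Genes that fell in metastases included Lgals2, a galectin (-4.47), Mfap5, a microfibril protein (-4.28, 20.7 ± 2.43 to 0.120 ± 0.208 FPKM), and Col17a1, a collagen of epithelial hemidesmosomes (-3.77, 21.6 ± 10.7 to 0.572 ± 0.433 FPKM). Mylpf, a fast muscle myosin light chain (-3.12), and C1qtnf3 (-2.97) fell. Gast, which encodes the hormone gastrin (-2.62, 75.2 ± 16.3 to 16.2 ± 12.2 FPKM), the sialyltransferase St6galnac2 (-2.56), the collagen-degrading protease cathepsin K, Ctsk (-2.43), and Gpx3, a secreted glutathione peroxidase (-2.02), fell as well. Mylpf stood at 106 and 117 FPKM in N134-RHAMMB tumours 2 and 4, the 2 with muscle transcripts, and at 11.0 FPKM in tumour 1. Gast lost its call without any 1 N134 tumour, or any 1 N134-RHAMMB tumour (adjusted p = 0.0577 to 0.129). It stood at 23.8, 2.09 and 22.6 FPKM in metastases 1, 2 and 3, so the size of its change rests partly on metastasis 2. Under the alternatives its log2 change ranged from -3.13 to -1.63. Mylpf lost its call without N134 tumour 1, or N134-RHAMMB tumour 2 or 4, or metastasis 1 or 3 (adjusted p = 0.0520 to 0.121). Gpx3 lost its call without N134 tumour 1, or N134-RHAMMB tumour 1 or 4, or metastasis 2 or 3 (adjusted p = 0.0513 to 0.119). Lgals2 lost its call without N134-RHAMMB tumour 1 (adjusted p = 0.0503). In metastases 1, 2 and 3 it stood at 55.6, 1.27 and 22.6 FPKM, so the size of its change also rests partly on metastasis 2.

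Markers of other liver cells were also higher. In the liver sinusoidal endothelial list 3 of 9 members rose over all genes and 5 adjusted over the list alone (median 0.45, adjusted p = 2.63e-04; adjusted p = 0.0842 with an estimated correlation). Clec4g was listed at 0 in all 6 subcutaneous tumours and at 3.70, 5.47 and 4.93 FPKM in metastases, and Stab2, a hyaluronan scavenger receptor, rose by 2.21. In the Kupffer list 2 members rose and 1 fell over all genes, and 3 rose and 1 fell adjusted over the list alone, of 9 (median 0.31, adjusted p = 0.0316; adjusted p = 0.562 with an estimated correlation). C6, a complement component, rose by 3.77. Clec4f was listed at 0 in all N134-RHAMMB tumours and at 1.93, 5.22 and 1.69 FPKM in metastases, and the folate receptor Folr2 fell by 1.89. Cholangiocyte genes rose in 3 of 6, and 3 adjusted over the list alone (median 0.92, adjusted p = 0.00239; adjusted p = 0.165 with an estimated correlation). They were Spp1, Pigr, the polymeric immunoglobulin receptor (3.60), and the water channel Aqp1 (1.72). Pericyte and stellate cell genes rose in 3 of 15, with 5 higher and 1 lower adjusted over the list alone (median 0.48, adjusted p = 0.00231; adjusted p = 0.547 with an estimated correlation). They were led by Colec11, a collectin (3.07), and Hgf, hepatocyte growth factor (1.32).

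In the set test 3 further lists were higher, with medians of 0.01, 0.18 and 0.42. Of 15 STAT3 targets, 3 rose over all genes and 3 adjusted over the list alone. They were Lcn2, lipocalin-2 (4.51), Fgl1, a secreted liver protein (4.03), and Cish, a cytokine signalling inhibitor (0.98). Whether liver tissue taken with the metastases supplied these transcripts was not tested. Of the 15 members, 8 had a log2 change above 0 and 7 below, and 4 stand in another list. The list's median was 0.01 and its mean 0.65 (adjusted p = 0.0469; adjusted p = 0.562 with an estimated correlation). Of 20 cholesterol synthesis genes, 1 rose, over all genes and adjusted over the list alone. Hsd17b7 stood at 0.46 (adjusted p = 0.361) and Sc5d at 0.44 (adjusted p = 0.425). The median was 0.18 (adjusted p = 0.0300; adjusted p = 0.666 with an estimated correlation). Y-linked genes had a median of 0.42 (adjusted p = 0.0316; adjusted p = 0.547 with an estimated correlation). In limma 1 of 3 rose over all genes, Ddx3y (0.63), and 2 adjusted over the list alone. Without metastasis 2 the cholesterol synthesis median turned to -0.06. The cholesterol synthesis list lost its call without N134-RHAMMB tumour 4, or metastasis 2 (adjusted p = 0.133 to 0.608). The STAT3 list lost its call without N134 tumour 1, or N134-RHAMMB tumour 1 or 2, or metastasis 1 or 3 (adjusted p = 0.0511 to 0.114). The Kupffer list lost its call without N134 tumour 3, or N134-RHAMMB tumour 4, or metastasis 2 (adjusted p = 0.0559 to 0.0970). The Y-linked list lost its call without N134-RHAMMB tumour 1, or metastasis 1 or 2 (adjusted p = 0.0665 to 0.0833). Cish lost its call without N134 tumour 1, or N134-RHAMMB tumour 1 or 2, or any 1 metastasis (adjusted p = 0.0681 to 0.156). Ddx3y lost its call without N134-RHAMMB tumour 1 or 2, or metastasis 1 or 3 (adjusted p = 0.0538 to 0.126).

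Fibroblast and matrix genes were lower in metastases (median -0.60, adjusted p = 0.00358; adjusted p = 0.562 with an estimated correlation). Over all genes 6 of 20 fell and 1 rose, and 8 and 2 adjusted over the list alone. Thy1, a surface glycoprotein of fibroblasts (-2.20), Fbln2, fibulin-2 (-1.66), and Fap, a fibroblast protease (-1.13), fell, whereas Dcn rose (1.23). Proteases and their regulators fell in 4 of 17, and 4 adjusted over the list alone (median -0.54, adjusted p = 0.00191; adjusted p = 0.562 with an estimated correlation), with Timp1 at -1.73 and Mmp2 at -1.12. Mmp3, stromelysin, was listed at 0 in all metastases and at 2.73, 2.01 and 2.16 FPKM in N134-RHAMMB tumours. Cell cycle genes were slightly lower (median -0.23, adjusted p = 6.07e-05; adjusted p = 0.534 with an estimated correlation). Over all genes 1 of 30 fell, the kinesin Kif20a (-0.54), and 9 adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, stood at -0.47 (adjusted p = 0.0739). Adipocyte genes fell in 3 of 9, and 5 adjusted over the list alone (median -0.65, adjusted p = 0.0300; adjusted p = 0.562 with an estimated correlation), with Cfd, adipsin (-2.14), and the fatty acid carrier Fabp4 (-1.44). Adipoq, adiponectin, was listed at 0 in all metastases and at 10.6, 1.75 and 0.822 FPKM in N134-RHAMMB tumours. Macrophage genes had a median of -0.40 (adjusted p = 0.0104; adjusted p = 0.646 with an estimated correlation). In limma 0 of 20 passed over all genes, 0 adjusted over the list alone and 6 at an unadjusted p under 0.05. Trem2 stood at -0.79 and Lyz2, lysozyme, at -0.77. Skeletal muscle genes were lower (median -2.75, adjusted p = 0.0219; adjusted p = 0.547 with an estimated correlation), with 1 of 3 lower over all genes, Mylpf, and 3 adjusted over the list alone. Tnni2 stood at -2.75 (adjusted p = 0.0786). Timp1 lost its call without N134 tumour 1, or any 1 N134-RHAMMB tumour, or metastasis 1 or 2 (adjusted p = 0.0582 to 0.140). Fap lost its call without N134-RHAMMB tumour 2 or 4, or metastasis 3 (adjusted p = 0.0545 to 0.0655). Mmp3 lost its call without N134-RHAMMB tumour 1 (adjusted p = 0.0612). The adipocyte list lost its call without metastasis 1 (adjusted p = 0.0750). The macrophage list lost its call without metastasis 3 (adjusted p = 0.101). The skeletal muscle list lost its call without metastasis 1 (adjusted p = 0.0554).

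The hyaluronan list did not pass (median -0.11, adjusted p = 0.417). In it Cd44 fell by 0.92 (adjusted p = 7.26e-04), 1 of 8 over all genes and 3 adjusted over the list alone. Vcan, the hyaluronan-binding proteoglycan versican, stood at -0.82 (adjusted p = 0.0991). Median, mean and test differed in sign for the neuronal list, which did not pass (adjusted p = 0.967). Of the 14 lists called, 1 held with an estimated correlation, the hepatocyte list. Fry called 13 lists, but not the same ones. They include the neutrophil and progenitor lists, which camera did not call (fry adjusted p = 0.01685 and 0.0269). Fry did not call the matrix, adipocyte, macrophage and cholesterol synthesis lists (fry adjusted p = 0.0696, 0.0714, 0.247 and 0.424). The gene count was 504 without N134-RHAMMB tumours 2 and 4, 1950 with library weights and 347 at a mean of at least 5 FPKM. With that filter the adipocyte median turned to 0.08.

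**Figure D3:**
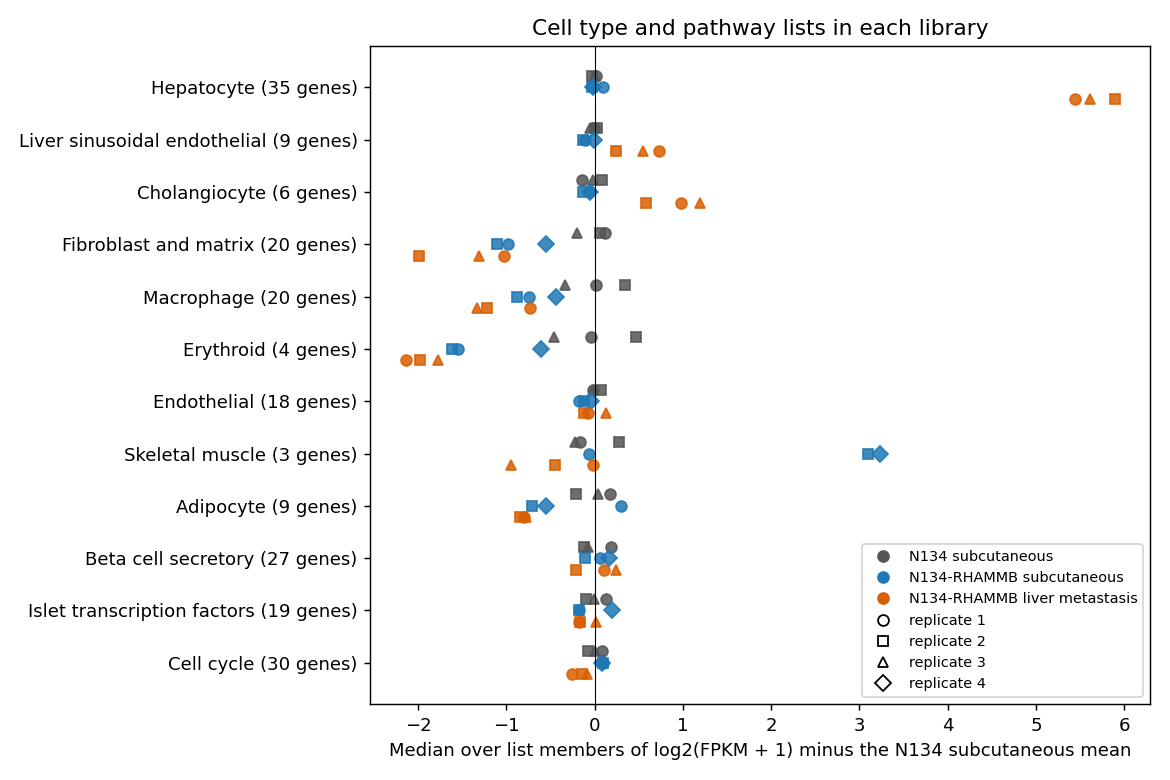
Median log2 difference from the mean of the N134 tumours for the members of selected gene lists, with 1 point per library on the log2(FPKM + 1) scale. The hepatocyte list lies between 5.44 and 5.90 in the 3 metastases, and the fibroblast and matrix list lies below the N134 tumours in all 6 N134-RHAMMB libraries, from -1.99 to -0.55.

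In the comparison of liver metastases of N134-RHAMMB with N134 subcutaneous tumours, cell line and site both differ, and their effects cannot be separated. Hepatocyte transcripts rose in 32 of 35 members, 33 adjusted over the list alone, with a median of 5.62 (camera adjusted p = 8.33e-62; adjusted p = 0.00334 with an estimated correlation). Gip fell the most, from 90.3 ± 5.39 FPKM (SD, n = 3) in N134 tumours to 0.135 FPKM in metastasis 1 and a listed 0 in metastases 2 and 3 (-6.45, SE 0.40, adjusted p = 1.04e-06). Fibroblast and macrophage transcripts fell in most members, 15 of 20 and 14 of 20. The set test calls of both lists were lost (adjusted p = 0.316 with an estimated correlation for fibroblasts, adjusted p = 0.398 with an estimated correlation for macrophages). Over all genes limma called 1276, 732 higher and 544 lower in metastases. With quantile normalization it called 758 higher and 821 lower.

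The genes that rose the most were Alb (9.34), Ahsg (8.27), Apoa1 (8.07), Hpx (7.98), Serpina3k (7.86), Apoa2 (7.23), Gstm3 (7.22), Serpinc1 (6.91), Cyp2e1 (6.84) and Fga (6.76). Alb went from 1.33 ± 0.241 to 1508 ± 99.2 FPKM, with adjusted p = 3.96e-11. Among genes at a mean of 5 FPKM or more in both groups, transferrin Trf (5.83, 22.5 ± 3.04 to 1336 ± 163 FPKM), the vitamin D binding protein Gc (5.58), C3 (4.87, 6.04 ± 1.85 to 202 ± 36.5 FPKM), Apoc3 (4.73) and haptoglobin Hp (4.11) led. In that subset 196 genes were higher and 269 lower. Genes that fell were Ccl8 (-6.09, 91.3 ± 52.7 to 0.179 ± 0.183 FPKM), Mfap5 (-5.04), C1qtnf3 (-3.55), the chemokine Ccl6 (-3.52) and Lgals2 (-3.44). The carbonyl reductase Cbr2 (-3.20), Thy1 (-3.08), Arhgap36 (-3.06) and Timp1 (-3.01, 35.1 ± 15.9 to 3.59 ± 2.29 FPKM) fell as well. Haem oxygenase Hmox1 (-2.74) and Gpx3 (-2.70) fell among genes at a mean of 5 FPKM or more in both groups. Lgals2 lost its call without any 1 N134 tumour, or any 1 N134-RHAMMB tumour, or metastasis 3 (adjusted p = 0.0528 to 0.112). The size of its change rests partly on metastasis 2, at 1.27 FPKM against 55.6 and 22.6 FPKM in metastases 1 and 3.

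Of the fibroblast and matrix list, 15 of 20 fell over all genes and 17 adjusted over the list alone (median -1.45, adjusted p = 4.48e-12; adjusted p = 0.316 with an estimated correlation), with Thy1, Fbln2 (-2.48) and Mmp2 (-2.29) in the lead. Macrophage genes fell in 14 of 20, 18 adjusted over the list alone (median -1.07, adjusted p = 2.31e-11; adjusted p = 0.398 with an estimated correlation), with Trem2 at -1.69 and Cd68, a lysosomal macrophage marker, at -1.40. Proteases and their regulators fell in 9 of 17, 12 adjusted over the list alone (median -1.05, adjusted p = 3.47e-06; adjusted p = 0.380 with an estimated correlation). Mmp3 was listed at 0 in all metastases, against 6.78, 10.4 and 2.42 FPKM in N134 tumours. Erythroid genes fell in 3 of 4, 3 adjusted over the list alone (median -1.99, adjusted p = 0.00109; adjusted p = 0.472 with an estimated correlation), with Hba-a1 at -2.1 and Hbb-bs at -2.02. Adipocyte genes fell in 5 of 9, 6 adjusted over the list alone (median -0.81, adjusted p = 0.00624; adjusted p = 0.589 with an estimated correlation), with Cfd at -2.82 and Adipoq listed at 0 in all metastases. Cell cycle genes fell in 3 of 30, 3 adjusted over the list alone (median -0.16, adjusted p = 0.00624; adjusted p = 0.589 with an estimated correlation), among them the mitotic kinase Cdk1 (-0.54). The kinesin Cenpe stood at -0.51 (adjusted p = 0.0787). Hypoxia and glycolysis genes fell in 3 of 23, 7 adjusted over the list alone (median -0.36, adjusted p = 0.0157; adjusted p = 0.815 with an estimated correlation). Adm, adrenomedullin, stood at -0.72 (adjusted p = 0.0803) and Aldoa, an aldolase, at -0.60 (adjusted p = 0.0789), while Pfkl (-0.52) and the pyruvate kinase Pkm (-0.51) fell. Pfkl lost its call without any 1 N134 tumour, or N134-RHAMMB tumour 1, or metastasis 1 or 3 (adjusted p = 0.0552 to 0.108). Pkm lost its call without N134 tumour 1 or 2, or any 1 N134-RHAMMB tumour, or metastasis 1 or 3 (adjusted p = 0.0536 to 0.155). The hypoxia list lost its call without N134 tumour 2 (adjusted p = 0.157). The cell cycle list lost its call without metastasis 1 (adjusted p = 0.0760).

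Of the lists of liver cells other than hepatocytes, cholangiocyte genes rose in 3 of 6, 3 adjusted over the list alone (median 0.78, adjusted p = 0.00424; adjusted p = 0.208 with an estimated correlation), with Pigr at 3.60 and Spp1 at 2.68. Sinusoidal endothelial genes rose in 3 of 9 and fell in 1, or 5 and 1 adjusted over the list alone (median 0.41, adjusted p = 0.00424; adjusted p = 0.208 with an estimated correlation), with Stab2 at 1.86, Oit3 at 1.81 and the scavenger receptor Stab1 at -0.79. Stab1 lost its call without any 1 N134 tumour, or metastasis 1 or 3 (adjusted p = 0.0630 to 0.0994). The Kupffer list did not pass and had a median of -0.23 and a mean of 0.17, with the test in the direction of the mean (adjusted p = 0.564). The 24 lists that did not pass, the Kupffer list among them, included beta cell secretory genes (median 0.01, mean -0.02, test upward, adjusted p = 0.853). Median, mean and test also differed in sign for the pericyte, STAT3, skeletal muscle and neutrophil lists. The hyaluronan list did not pass (median -0.05, adjusted p = 0.780), with Vcan at -1.19 and Cd44 at -0.49. Vcan lost its call without N134 tumour 1 or 2 (adjusted p = 0.0517 to 0.0599). Cd44 lost its call without any 1 N134 tumour, or N134-RHAMMB tumour 1 or 4, or metastasis 1 or 3 (adjusted p = 0.0508 to 0.145). Camera with an estimated correlation kept 1 of 10 calls, the hepatocyte list. Fry called 11 lists, among them the Kupffer and other islet hormone lists, which camera did not call (fry adjusted p = 0.0310 and 0.00525). Fry did not call the hypoxia list (fry adjusted p = 0.107). The gene count was 594 at a mean of at least 5 FPKM, where the sinusoidal endothelial median turned to -0.06, and 758 with an absolute log2 change of at least 1.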

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

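The test of leaving out N134-RHAMMB tumours 2 and 4 was chosen after the data were seen, and the other alternatives before. Of 458 results for single genes, 246 kept their direction and side of the threshold under all alternatives, and none reversed. Of 36 list calls, 2 held under all, the hepatocyte list in both comparisons with metastases. A reversal is counted only where the value or its alternative passed, and list results cover only lists called. Over genes and alternatives, 4546 of 4888 values kept their side of the threshold, 165 lost and 177 gained a call. With 1 library left out these were 3794 of 4122, 258 and 70. List calls were lost in 85 of 427 values and, with 1 library left out, in 29 of 324. Of the genes selected by size, 68 to 94 of 94 kept their call. At a mean of at least 5 FPKM the counts of genes were 15, 347 and 594 (N134-RHAMMB against N134 tumours, metastases against N134-RHAMMB tumours, metastases against N134 tumours), with fewer genes tested. There the adipocyte median of the second reversed to 0.0812 and the sinusoidal endothelial median of the third to -0.0602. Library weights gave 2629 and 1950 genes in the first and second, Hmmr changes of 0.2508 and -0.3634 that passed, and a cholesterol synthesis median of -0.1073 in the second. The cause was not tested. The 6 subcutaneous libraries alone gave 169 genes in the first, and a log2 change of at least 1 left 758 in the third. Without N134-RHAMMB tumours 2 and 4, which leaves 1 library assumed to vary like the other groups, the first and second gave 1 and 504.

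Leaving out 1 library at a time gave 0 to 193 genes in the first comparison, and the cholesterol synthesis median of the second ranged from -0.0609 (without metastasis 2) to 0.4106. The replicate number as a block left 1 gene in the first. Deviations from the group means correlated by -0.00270 to 0.102 in 7 same-numbered pairs and by -0.195 to 0.150 in 20 other pairs. These ranges overlap and do not settle whether the numbers pair the samples. With an estimated correlation camera called 0, 1 and 1 lists, with 4, 3 and 4 at an unadjusted p under 0.05, and fry called 1 in the first. Camera has no robust option, so that alternative gives no list value. Values near the FPKM of 1 fragment are set by counting error, and depth limits the genes listed at 0.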

Other observations

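The tests of explanations and of other splits of the libraries were chosen after the results were seen. Immune, developmental and adhesion genes moved singly in metastases against N134-RHAMMB tumours, in lists that did not pass. B2m, the invariant chain of class I molecules, rose by 1.03 and Nlrc5, a transactivator of class I genes, by 1.13. They were 2 of 13 class I genes over all genes and 2 adjusted over the list alone (median 0.01, adjusted p = 0.304). Among interferon response genes, Bst2, tetherin, rose by 1.03 and Usp18 fell by 0.62 (median 0.12, adjusted p = 0.235), 1 and 1 of 23, likewise 1 and 1 adjusted over the list alone. In the progenitor list Id3, an inhibitor of helix-loop-helix factors, rose by 1.33 and Cd24a fell by 0.91. Over all genes 2 of 11 rose, with Spp1, and 1 fell, or 4 and 2 adjusted over the list alone (median 0.37, adjusted p = 0.0527). Cldn3, a tight junction protein, rose by 2.46, 1 of 15 adhesion genes over all genes, with 2 higher and 1 lower adjusted over the list alone. The median was -0.07 and the mean 0.01, with the test in the direction of the mean (adjusted p = 0.980).

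Islet genes changed in few members in the same comparison. Pax4, an islet transcription factor, fell by 1.73 and Mafa, an activator of insulin transcription, rose by 0.91, 1 and 1 of 19, over all genes and adjusted over the list alone (median 0.01, mean -0.10, test in the direction of the mean, adjusted p = 0.615). Chgb, chromogranin B of secretory granules, fell by 1.36, 1 of 27 beta cell secretory genes over all genes and 1 adjusted over the list alone. The median was -0.09 and the mean -0.04, while the test pointed upward (adjusted p = 0.875). Dusp4, a phosphatase that limits ERK, fell by 1.20, 1 of 16 ERK targets over all genes and 1 adjusted over the list alone (median -0.18, adjusted p = 0.417). Mafa lost its call without N134-RHAMMB tumour 1, or metastasis 1 or 3 (adjusted p = 0.0760 to 0.10). Dusp4 lost its call without N134-RHAMMB tumour 1 or 4 (adjusted p = 0.0873 to 0.0933).

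Hepatocyte transcripts rose in metastases, 88.6% of the list against N134-RHAMMB tumours, which is consistent with liver tissue taken with the metastases, as are the 5 of 18 Kupffer and sinusoidal endothelial genes that rose (C6, Clec4f, Clec4g, Oit3 and Stab2), although 1, Folr2, fell. The most abundant hepatocyte genes reached 1508 ± 99.2 (Alb) and 1336 ± 163 (Trf) FPKM in metastases, 18 of 35 list members had a mean of at least 1 FPKM in N134-RHAMMB tumours already, and 1 stands in another list. Scaling between libraries as the cause was argued against, since the hepatocyte median stayed at 5.60 with median-of-ratios scaling. Liver genes switched on in the tumour cells may add to the change, which these whole-tissue libraries do not test.

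Fibroblast and macrophage lists were lower in N134-RHAMMB than in N134 tumours in a set test at a preset correlation, a call lost for both (adjusted p = 0.375 with an estimated correlation), with 2 and 0 of 20 members passing over all genes in limma and 16 and 17 at an unadjusted p under 0.05. To look at a lower share of all host cells alike, 2 lists were compared. The mean change was -0.78 for fibroblast and -0.11 for endothelial genes, so these 2 did not fall alike. Macrophage, erythroid and pericyte medians were lower too (-0.67, -1.21 and -0.35). The 2-sided permutation p = 1e-05 was the smallest that 100000 resamples can give. It decides nothing, since the lists were chosen after their medians were seen and the permuted genes are not independent. Scaling was argued against, since the fibroblast median stayed at -0.86 with median-of-ratios scaling. RHAMMB and another difference between the cell lines cannot be told apart with 1 RHAMMB cell line in the design. A change in the fibroblasts and macrophages themselves, or in their share alone, may also account for it and was not tested.

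Metastasis 2 stood apart: 19 genes were at least 4-fold above and 67 below the mean of metastases 1 and 3, against 3 and 3 for metastasis 1 and 6 and 5 for metastasis 3, all set against the other 2 (genes in which those differed by a log2 of less than 1). In metastases 1, 2 and 3, Cntn1 (0.0979, 19.1 and 0.0511 FPKM) and Ucn3 (0.498, 22.4 and 0.555 FPKM) were high and Tex101 (107, 0.778 and 209 FPKM) and Basp1 (36.5, 0.974 and 29.6 FPKM) low in metastasis 2, examples chosen after their values were seen. A different share of liver tissue and lower depth were argued against, since its hepatocyte median differed by 0.179 and its estimated depth was 106% of the deeper other metastasis. A candidate explanation is growth from different tumour cell clones that are mixed in the subcutaneous tumours. Of genes picked as high in metastasis 2 against metastasis 1, 25 of 30 were lower in metastasis 3 than in N134-RHAMMB tumours. Of genes picked as low, 29 of 93 were (2-sided Fisher's exact p = 5.55e-07). The other way round the counts were 30 of 34 and 31 of 87 (Fisher's exact p = 1.44e-07). By comparison, 53.5% of all genes were lower in metastases 1 and 3 than in those tumours. Metastases 1 and 3 were alike (Pearson's r = 0.979), so picking genes by one largely set their level in the other. Any departure from the subcutaneous tumours that metastases 1 and 3 share would pass, so the test cannot single out clones. The test replaced an earlier one that read the direction in the libraries used for picking (Fisher's exact p = 1.57e-09). The picking itself favoured that outcome, so the earlier test decides nothing. Genes are not independent, no genotype was tested, and different regulation in metastasis 2 stays open.

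Dividing the 6 libraries of a comparison into 3 against 3 gives 10 splits with the real one, too few for a share under 0.05. For N134-RHAMMB against N134 tumours the real split called 25 genes and the highest other 4. For metastases against N134-RHAMMB tumours and against N134 tumours the real split called 843 and 1276 genes, and each of the other splits 0 in limma, with 191 to 1615 and 336 to 1198 genes at an unadjusted p under 0.05.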
